A study of Mus musculus with 6 samples.

How the data were processed

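RNA from the livers of 10-week-old male BALB/c mice was hybridised to Affymetrix genome-wide mouse expression arrays, 1 array per sample. Per the labels, 3 samples came from control mice and 3 from mice kept singly for 30 days. The mice entered the study at 4 weeks of age, were housed 5 per cage, and had 10 days to acclimatise before isolation began. Isolated mice also had less bedding than controls, and all mice had free access to water and a standard diet. The time of day at which livers were taken and the time since the last meal are not given in the sources used here.

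Per the labels' protocols, total RNA was extracted with TRIzol, purified on RNeasy columns and converted to biotinylated cRNA from 2 µg of RNA. Per the submitters' processing notes, the deposited intensity values came from MAS5, the Affymetrix algorithm that gives a linear signal per probe set from its perfect-match and mismatch probes. The scaling target, detection calls and software version are not given in the sources used here. MAS5 signals of dim probe sets are noisy, so a filter and a pseudocount were applied. The 2% trimmed mean signal ran from 92 to 110 over the 6 arrays, so the arrays did not share 1 value after the authors' processing. That scale was kept, and centring and quantile normalization were tried as alternatives.

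The table held 45101 probe sets. The 64 control probe sets were set apart, which left 45037. A pseudocount of 2, the 10th percentile of all values rounded to a whole number, was added before taking log2. Fold changes are therefore on the log2(value + 2) scale and understate the change of dim probe sets. Probe sets in the upper 50% by mean log2 value over all 6 arrays were tested, 22519 in all, with a floor at a mean log2 value of 4.32. With limma 3.58.1 in R 4.3.3, a linear model with 2 groups was fitted, and eBayes moderated the variances with a trend on mean intensity. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a call at an adjusted p under 0.05.

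Gene names came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of these, 34754 matched a RefSeq gene table of assembly GRCm38.p6 by gene identifier, which changed 0 symbols and was used for names only. No genome build is named with the arrays, so no coordinates are given. A gene was represented by its tested single-symbol probe set with the highest mean, which gave 10986 genes. No gene was named from a probe set with several symbols.

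Before the data were examined, 22 pathway lists and 11 lists of cell type markers were fixed, along with the tests, the alternatives and the rule for naming genes. Of the 658 list genes, 1 could not be matched to a symbol. The 26 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 26. Camera with an estimated correlation, and fry, stood beside it. Named genes were, per direction, the 12 with the largest log2 change among called genes whose groups did not overlap. Up to 4 members of each list with a passing test or a called member were added, up to 2 members of each other list, and the RNA quality probe sets. Ratios of 3′ to 5′ control probe sets were compared by an exact permutation test.

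The procedure was tested on simulated data for isolated against control with 22519 probe sets, of which 200 were changed. It recovered 60% of those changed by 1 log2 unit and 90% of those changed by 2, made 156 calls of which 6 were false, and made 0 calls with nothing changed. The simulated noise was normal, independent between probe sets, and had a spread that followed a trend on mean intensity, as the fit assumes. The simulation therefore checks the procedure under its own variance model and cannot give the share of false calls in the real data. Alternatives covered the pseudocount, the filter, the normalization, the variance model, array weights, the replicate number as a block, the probe set per gene, the threshold, the test, the inter-gene correlation and each array left out. Leaving out isolated replicates 2 and 3 together was added after the data were seen, and assumes that the 1 isolated array left varies like the controls. With 3 arrays per group, the number of arrays limits the precision, and an exact test cannot give a p under 0.1. Figures were drawn with matplotlib 3.10.9.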

Results

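Hepatic gene expression was compared between control mice and mice exposed to social stress by 30 days of isolation, with 3 arrays per group. The median signal per array was 18.4, 21.8 and 22.1 in controls and 19.4, 18.4 and 21.9 in isolated mice. Over the tested probe sets, the log2 values of arrays of 1 group correlated at 0.97 in each pair, and arrays of different groups at 0.95 to 0.97. These correlations are across probe sets, which are not independent replicates. The labels number the samples of each group but do not say that each array came from a separate mouse. The spread between these samples may therefore be partly technical. Limma p-values rest on that spread only in part, as the variance trend weighed as 16.1 degrees of freedom against 4 from the arrays. Genes that vary more than the trend thus get a smaller SE. For Pdk4 and Igfbp1 it was 0.347 and 0.384 on the log2 scale, against 0.6 and 0.757 with a robust trend.

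Isolated livers had higher transcript levels of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and of the lipogenic transcription factor gene Srebf1. They had lower levels of Pdk4, which encodes an inhibitory kinase of pyruvate dehydrogenase, and of Igfbp1, an insulin-repressed binding protein of insulin-like growth factors. The Cyp7a1 signal rose from 637 ± 354 to 3360 ± 1210 (SD, n = 3 per group), a 5.51-fold change with a limma adjusted p of 3.23e-05. That of Srebf1 rose from 258 ± 76.9 to 1380 ± 447, or 5.26-fold, with a limma adjusted p of 2.85e-06. That of Pdk4 fell from 413 ± 263 to 21.3 ± 4.71, a 15.3-fold difference with a limma adjusted p of 1.34e-06. Igfbp1 fell from 1350 ± 644 to 107 ± 97.8, a 14.9-fold difference with a limma adjusted p of 4.93e-06. In limma fits with a robust trend, Cyp7a1 (adjusted p 0.2), Pdk4 (0.0709) and Igfbp1 (0.148) did not pass, and without the intensity trend Cyp7a1 did not pass (0.0797), while Srebf1 passed in both (0.00233 and 0.038). The fold of Pdk4 was 22.9 without control replicate 1 and that of Igfbp1 24 without isolated replicate 3. Both changes were smaller without control replicate 2, at log2 -3.453 for Pdk4 and -3.529 for Igfbp1, against -3.931 and -3.894 over all arrays.

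In all, 174 probe sets were higher and 193 lower in isolated mice among 22519 tested, at a limma adjusted p under 0.05. By the probe set that represents each gene, 99 genes rose and 93 fell. Of the 367 called probe sets, 363 separated the groups without overlap, as did 15.4% of all tested probe sets against the 10% that chance gives. The median log2 change over all tested probe sets was 0.035.

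Besides Cyp7a1 and Srebf1, the genes with the largest increases included Angptl8, a secreted regulator of lipoprotein lipase, which rose 5.18-fold, and Mid1ip1, an activator of acetyl-CoA carboxylase, which rose 4.14-fold. Tsc22d1 rose 3.62-fold, and Rcan1, an inhibitor of calcineurin, rose 3.48-fold. Cxcl11, an interferon-inducible chemokine, rose 4.36-fold from a low signal of 21.5 ± 15.4 to 77.5 ± 5.9. Snai2 rose 3.89-fold, Rrp9 3.65-fold, Zfp324 3.22-fold, Vasn 3.13-fold and Zdhhc12 3.05-fold. The other tested probe set of Vasn had a log2 change of 0.27 and was not called. Among these 12 genes, the highest limma adjusted p was 0.0287, for Zfp324. Angptl8, Cxcl11 and Snai2 did not pass without the intensity trend or with a robust trend (adjusted p 0.0657 to 0.379), nor did Rrp9, Zfp324, Vasn and Zdhhc12 without the trend (0.101 to 0.158). The fold of Cxcl11 was 2.45 without control replicate 2, and those of Rrp9 and Zfp324 are approximate, as their control signals of 10.2 and 13.1 lie under the floor of 18 that the filter sets on the mean signal, and no detection calls are at hand.

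Among the genes with the largest decreases, the cell cycle repressor E2f8 fell 8.69-fold, from a signal of 251 ± 45.1 to 31.5 ± 23.4. Txnip, an inhibitor of thioredoxin, fell 6.86-fold, from 1580 ± 85.4 to 236 ± 72.2, and its other tested probe set fell by 2.67 on the log2 scale. The metallothionein Mt1 fell 6.93-fold, the mitochondrial carrier Slc25a30 fell 6.58-fold, and Fgf21, a hormone secreted by the liver, fell 6.45-fold. Rgs16, a regulator of G protein signalling, fell 6.28-fold and Ppp1r3g, a glycogen-targeting phosphatase subunit, fell 6.09-fold. Depp1 fell 5.21-fold, the small Maf protein gene Maff 4.39-fold and Fos 4.24-fold. Among the 12 genes with the largest decreases, the highest limma adjusted p was 0.0158, for Maff. Mt1, Slc25a30, Rgs16, Ppp1r3g, Depp1 and Maff did not pass without the trend or with a robust trend (adjusted p 0.0951 to 0.434), nor did Fos without the trend (0.0704). With 1 array left out, the fold was 13.1 for Mt1 (without control replicate 1), 3.76 for Slc25a30 and 3.64 for Ppp1r3g (without isolated replicate 2), 4.18 and 11.8 for Rgs16 (without isolated replicates 2 and 3, each in turn), and 2.75 and 6.7 for Maff (without isolated replicates 1 and 3, each in turn). The change of Mt1 was smaller without control replicate 2, at log2 -2.286 against -2.793 over all arrays. The folds of Fgf21, Ppp1r3g, Maff and Fos are approximate, as their isolated signals of 17.6, 17, 15.7 and 14.1 lie under the same floor.

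**Figure D1:**
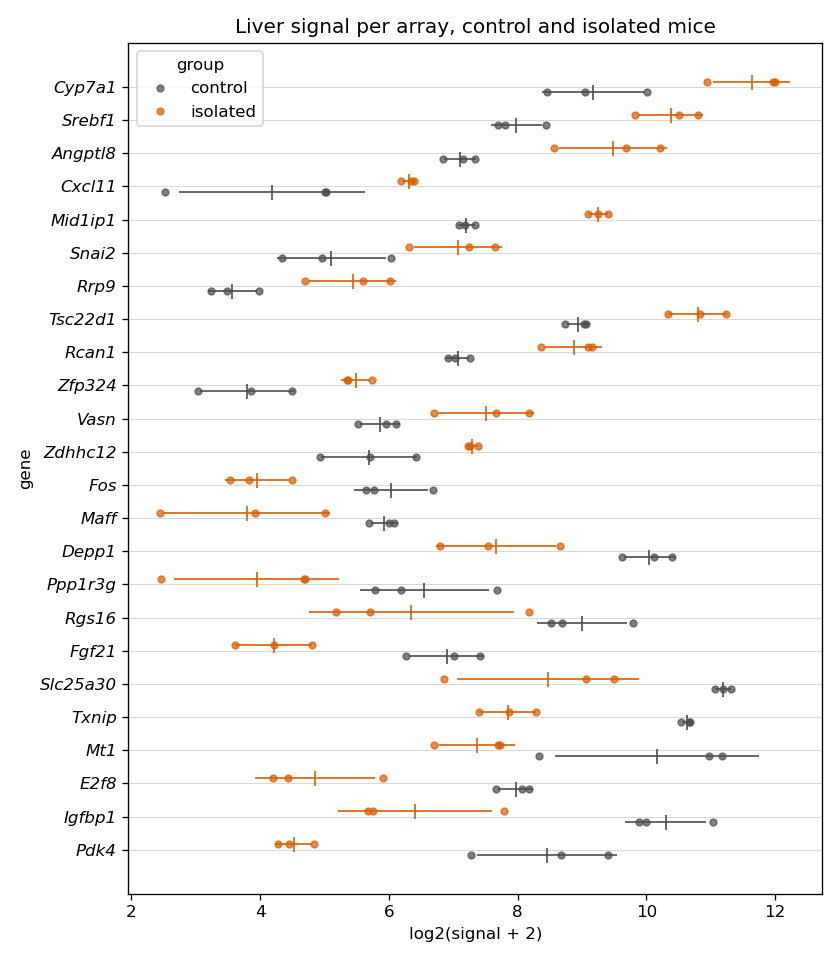
Signal per array of the 24 genes with the largest changes, 12 in each direction, as log2(signal + 2) on the horizontal axis with 1 gene per row. Each point is 1 array (3 control, grey, and 3 isolated, orange), the tick is the group mean and the bar 1 SD; the groups do not overlap in any of these genes, which were chosen for that.

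The number of calls depended on the variance model: without the intensity trend, 15 probe sets were higher and 16 lower, and 9 of the 24 genes with the largest changes kept their call, while a robust trend kept 12 of the 24. Without a filter 81 were higher and 101 lower, and higher calls numbered 115 without control replicate 2 and 97 without isolated replicate 3, while lower calls numbered 82 without control replicate 3.

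Genes activated by PPARalpha, the fatty acid sensor that turns on lipid oxidation in fasting, were lower in isolated mice. Of 23 tested members, 11 fell, 0 rose and 12 did not pass, and 12 fell when adjusted over the list alone. Besides Pdk4 and Fgf21, Angptl4, an inhibitor of lipoprotein lipase, fell 4.2-fold and Acot1, an acyl-CoA thioesterase, fell 3.45-fold. The median log2 change of the list was -0.75, and camera gave an adjusted p of 1.64e-21, or an adjusted p of 0.568 with an estimated correlation. Without the intensity trend 9 of the 11, Angptl4, Acot1, Acot3 and Cyp4a14 among them, did not pass (adjusted p 0.0585 to 0.264), and with a robust trend Angptl4, Pdk4 and Cyp4a14 did not (0.0699 to 0.29). Without control replicate 3, 7 members fell. Mitochondrial beta-oxidation genes passed camera in the same direction with an adjusted p of 0.0443, or an adjusted p of 0.811 with an estimated correlation. Of its 18 tested members 0 were called, also when adjusted over the list alone, and the median log2 change was -0.09. A second probe set of the member Hadhb, named after its values were seen, was called lower, with a log2 change of -1.155 and a limma adjusted p of 0.00326, against -0.29 for the one that represents the gene. The camera call was lost without control replicate 1 (adjusted p 0.0698), control replicate 3 (0.176, with a median of 0.0006), isolated replicate 1 (0.162) and isolated replicate 2 (0.0594). The member with the smallest p, Eci2, had a log2 change of -0.35 ± 0.16 (SE) with a limma adjusted p of 0.392.

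Of 25 tested genes of fatty acid and triglyceride synthesis, 6 rose and 0 fell, and 6 rose and 1 fell when adjusted over the list alone. These were Srebf1, Mid1ip1, Fasn, Thrsp, Elovl6 and Scd2. Fasn, the fatty acid synthase, rose 2.29-fold from 461 ± 3.21 to 1070 ± 179. Thrsp, a lipogenic regulator, rose 1.55-fold. A second probe set of Lpin1, named after its values were seen, was called lower, with a log2 change of -1.136 and a limma adjusted p of 0.0153, against -0.716 and 0.244 for the one that represents the gene; its call was lost without control replicate 3 (0.108) and without isolated replicate 1 (0.0503). Without the intensity trend Fasn, Thrsp, Elovl6 and Scd2 did not pass (adjusted p 0.0621 to 0.307). The camera adjusted p was 0.00108, or an adjusted p of 0.669 with an estimated correlation. The median log2 change of the list was only 0.08 and the mean 0.31, with 17 members above 0 and 8 below, so the rise was not shared by the whole list. Markers of fat tissue moved on some of the same arrays. Adipoq, below the filter and so not tested, read 4.38, 8.48 and 15.6 in controls and 3.78, 59.5 and 54.8 in isolated replicates 1, 2 and 3, and Retn read 2.39, 2.78 and 3.88 against 2.65, 20 and 42.2. Fabp4, another fat marker, passed upward when adjusted over the adipocyte list alone but not over all probe sets, where it passed in 2 of the fits with 1 array left out. Plin4 fell 2.69-fold (limma adjusted p 0.00695), and Lipe had a log2 change of -0.16 (-0.37 without isolated replicate 2 and 0.10 without isolated replicate 3). Lep and Cidea, also below the filter, read 2.07 ± 1.24 and 11.7 ± 7.48 in controls against 1.89 ± 1.16 and 9.56 ± 6.85 in isolated mice. Without isolated replicates 2 and 3, a fit chosen after seeing the data, 11 PPARalpha target genes fell, including 10 of the original 11, and 3 synthesis genes rose; it rests on 1 isolated array, assumed to vary like the controls, on which 6 of the 6 synthesis genes lay above every control, with a median log2 change of 1.06 against 1.16 over all arrays. Without isolated replicate 3 alone, 3 synthesis genes rose.

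Glucocorticoid-responsive genes included 6 that fell and 0 that rose of 22 tested. Adjusted over the list alone, 10 fell and 1 rose. The 6 were Igfbp1, Angptl4, Klf9, Mt1, Fkbp5 and Mt2, of which Angptl4 is also in the PPARalpha list. Klf9, a Krüppel-like transcription factor induced by glucocorticoids, fell 2.18-fold, and its 5 other tested probe sets were also called lower. The camera adjusted p was 1.63e-08, or an adjusted p of 0.568 with an estimated correlation. With a robust trend 2 of the 6, Klf9 and Fkbp5, passed, and without the intensity trend Igfbp1 alone did, with adjusted p of 0.062 to 0.322 for the other 5. Without isolated replicate 3, 10 fell.

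Immediate early genes, which are switched on fast by stimuli, were lower, with 4 of 19 members falling and 0 rising, the same counts as when adjusted over the list alone. Egr1 fell 3.56-fold, Gadd45b 2.73-fold and Jun 1.81-fold, besides Fos. The camera adjusted p was 9.02e-06, or an adjusted p of 0.568 with an estimated correlation. Without the intensity trend none of the 4 passed (adjusted p 0.0704 to 0.193), and without control replicate 2, 2 members fell.

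Of 23 genes of the unfolded protein response, 3 rose and 1 fell, and 9 rose and 2 fell when adjusted over the list alone. The secreted endoplasmic reticulum proteins Manf and Creld2 rose 1.91-fold and 2.41-fold, and the chaperone Hspa5 rose 1.42-fold. Chac1, a glutathione-degrading enzyme induced through ATF4, fell 2.52-fold. The camera adjusted p was 4.98e-05, upward, or an adjusted p of 0.669 with an estimated correlation. Without the intensity trend none of the 4 passed (adjusted p 0.184 to 0.36), and with a robust trend Creld2 (0.47) and Chac1 (0.0528) did not. With quantile normalization or median centring, 1 member rose. Without isolated replicates 2 and 3, which leaves 1 isolated array, 0 rose and the camera adjusted p was 0.376, with the median log2 change still above 0, at 0.15.

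In the list of bile acid synthesis and transport, Cyp7a1 rose and Nr0b2, a repressor of Cyp7a1, fell 2.73-fold from 1170 ± 125 to 445 ± 159, while the other 19 members did not pass. The Cyp7a1 call ended with a robust trend (adjusted p 0.2) and without the trend (0.0797), and the Nr0b2 call without the trend (0.106). The counts were 1 and 1 also when adjusted over the list alone, and the camera adjusted p was 0.461. In cholesterol synthesis, Mvd rose 1.98-fold and 19 of 20 members did not pass (camera adjusted p 0.34), with the same count when adjusted over the list alone. A second probe set of Sc5d, named after its values were seen, was called higher, with a log2 change of 0.8392 and a limma adjusted p of 0.0157, a call lost without control replicate 3 (0.0688) and without isolated replicate 2 (0.0759). The call on Mvd was lost in 4 of the fits with 1 array left out and without the trend (0.18). In lipoproteins and lipid transport, Angptl4 was the 1 call among 23 tested members, also when adjusted over the list alone (camera adjusted p 0.0886), and it did not pass without the trend (0.062) or with a robust trend (0.0699).

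Other lists held few calls. Of 26 xenobiotic metabolism genes, Cyp2c38 rose 1.74-fold, with 3 rising when adjusted over the list alone (camera adjusted p 0.317). Of 21 genes of insulin and growth hormone signalling, Igfbp1 and Socs2 fell, also when adjusted over the list alone (camera adjusted p 0.0886). Of 17 circadian clock genes, Nfil3 fell 1.89-fold, with 3 falling when adjusted over the list alone (camera adjusted p 0.317). A second probe set of Rora, named after its values were seen, was called lower, with a log2 change of -0.8542 and a limma adjusted p of 0.0214, a call lost without control replicate 1, 2 or 3 or isolated replicate 3 (0.057 to 0.0824). Socs2, an inhibitor of growth hormone signalling that fell 3.98-fold (6.41-fold without isolated replicate 1 and 2.27-fold without isolated replicate 2), was the 1 call among 16 male-biased liver genes, of which 15 had log2 changes below 0; 3 fell when adjusted over the list alone, and the camera adjusted p was 0.000105, or an adjusted p of 0.669 with an estimated correlation. Acot3 and Cyp4a14, both also PPARalpha targets, were the 2 that fell of 11 female-biased genes, also when adjusted over the list alone (camera adjusted p 0.0751). Without the intensity trend Cyp2c38, Nfil3, Socs2, Acot3 and Cyp4a14 did not pass (adjusted p 0.0797 to 0.301), and with a robust trend Igfbp1, Socs2 and Cyp4a14 did not (0.148 to 0.53).

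The acute phase response list was lower by camera, with an adjusted p of 9.02e-06, or an adjusted p of 0.673 with an estimated correlation. Of its 26 members the 1 call was Orm2, which rose 2.47-fold, against the list's direction. Adjusted over the list alone, 1 rose and 2 fell. Steap4, a metalloreductase, read 1410 ± 483 and 843 ± 232 with a limma adjusted p of 0.144. Interferon response and antigen processing genes were higher by camera (adjusted p 0.0315, or an adjusted p of 0.811 with an estimated correlation). Igtp, an interferon-inducible GTPase, rose 1.8-fold as the 1 call of 27, and 2 rose when adjusted over the list alone. Without the intensity trend Orm2 (adjusted p 0.111) and Igtp (0.199) did not pass. The camera call was lost without control replicate 3 (adjusted p 0.176) and without isolated replicate 3 (0.207), where the median log2 change went from 0.21 to 0.013.

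No member was called by limma in gluconeogenesis and amino acid breakdown (21 tested), cytosolic heat shock response (18), antioxidant and NRF2 target genes (22), cell cycle (15), oxidative phosphorylation (37) or cytosolic ribosomal proteins (24). Adjusted over the list alone, gluconeogenesis had 2 that rose and 1 that fell, heat shock and antioxidant genes 1 that fell in each, and the other lists 0. The camera adjusted p was 0.317, 0.966, 0.558, 0.317, 0.524 and 0.317 in that order. Pck1, the gluconeogenic enzyme, had a log2 change of -0.41 ± 0.14 (SE) with a limma adjusted p of 0.204, and G6pc of -0.66 ± 0.19 with 0.0881. Their log2 changes were -0.59 and -0.90 without isolated replicate 3, and -0.26 and -0.37 without isolated replicate 1. With 1 array left out, Pck1, G6pc, Hal, Hspa1a, Gclc and Mcm2 each gained a call in 1 fit. The median and mean log2 change and the direction given by camera differed in sign for the bile acid, circadian clock, heat shock, antioxidant and hepatocyte lists, in which camera did not pass.

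Among cell type markers, Kupffer cell and macrophage genes were lower by camera with an adjusted p of 0.0142, or an adjusted p of 0.811 with an estimated correlation, and 0 of 14 members were called. That camera call was lost without control replicate 3 (adjusted p 0.0637) and without isolated replicate 2 (0.126). Slc40a1 had a log2 change of -0.33 ± 0.17 (SE) and Cd5l of -0.32 ± 0.21, with limma adjusted p of 0.478 and 0.645. Camera did not pass for liver endothelial cells (adjusted p 0.317), stellate cells and fibroblasts (0.168) or hepatocytes (0.919), and 0 of 12, 11 and 13 members were called. Adjusted over the list alone, 1 hepatocyte gene rose and no gene of the other 3 lists passed. Too few members of the remaining lists were tested. Of 4 tested adipocyte genes, Plin4 fell 2.69-fold, Fabp4 had a log2 change of 0.90 ± 0.23 (SE) with a limma adjusted p of 0.0578, and Lipe and, by the probe set that represents it, Car3 were not called, while 2 dimmer Car3 probe sets, named after their values were seen, were called higher by log2 changes of 3.28 and 3.94 (3.19 for the latter without control replicate 2). Adjusted over the list alone, Fabp4 rose and Plin4 fell. Plin4 did not pass without the intensity trend (adjusted p 0.11). In controls Car3 had a signal of 11600 ± 565, so the liver itself expresses that marker. The tested T, B and NK cell (1), neutrophil (2), cholangiocyte (3), erythroid (1) and exocrine pancreas (2) genes were not called, and 0 skeletal muscle genes were tested.

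**Figure D2:**
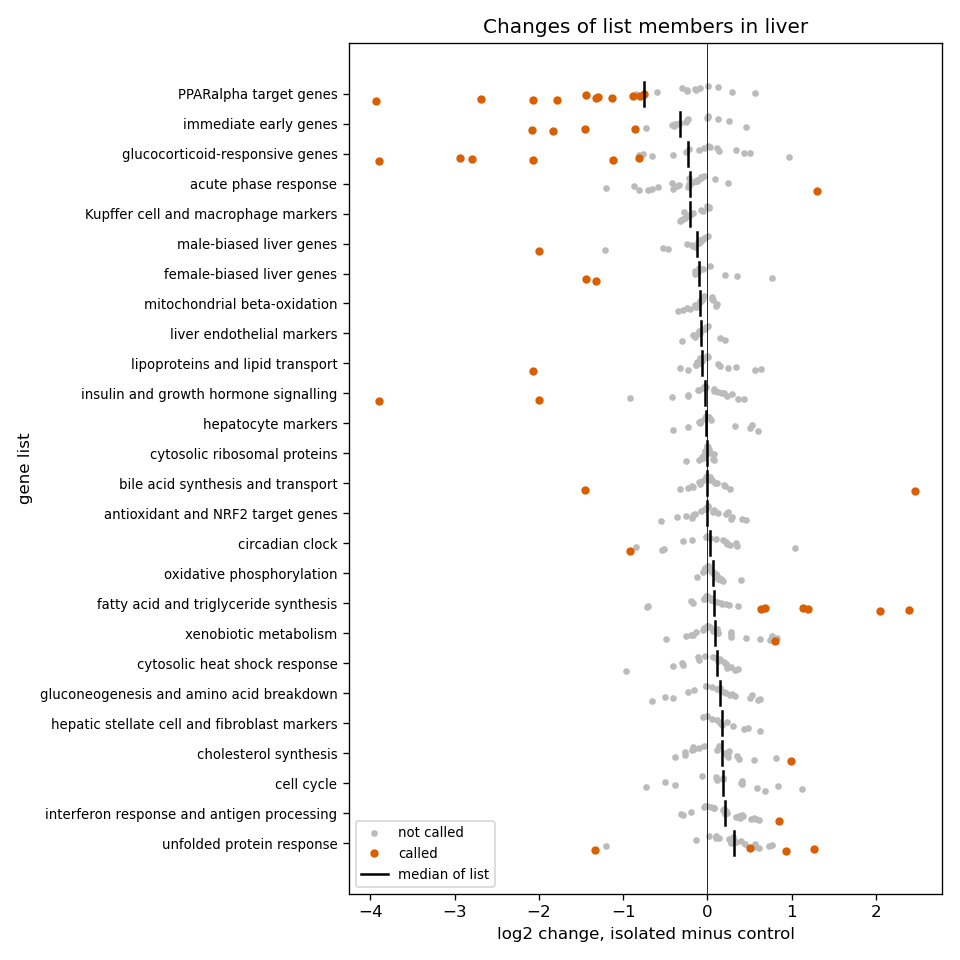
Log2 change, isolated minus control, of each tested member of the 26 lists on the horizontal axis, with 1 list per row, ordered by median. Orange points are members called by limma, grey points members not called and black bars the medians, of which that of the PPARalpha target genes, -0.75, is the lowest.

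List calls by camera rest on the preset correlation: 10 lists passed with it and 0 with an estimated correlation or by fry. Other splits of the 6 arrays into 2 groups of 3 passed up to 12 lists. Of the 10 splits, the real split included, 2 gave a camera p as small as that of the real split for the acute phase list. For the unfolded protein response, interferon, beta-oxidation and Kupffer cell lists, 3 of the 10 did. For the PPARalpha, fatty acid synthesis, glucocorticoid, male-biased and immediate early lists the real split alone did, and 10 splits are too few for a share under 0.05. With 1 array left out, some lists that had not passed did so by camera. Without control replicate 2 these were cholesterol synthesis (adjusted p 0.0117), lipoproteins (0.0215), female-biased genes (0.0242), insulin and growth hormone signalling (0.00633) and stellate cell markers (0.0068). Without isolated replicate 1 they were cholesterol synthesis (0.0226), female-biased genes (0.0104), insulin and growth hormone signalling (8.29e-05) and stellate cell markers (0.0153). Xenobiotic metabolism passed without control replicate 1 (0.0267) or isolated replicate 3 (0.033), insulin and growth hormone signalling without isolated replicate 3 (0.033), and female-biased genes without isolated replicate 2 (0.0443).

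Of the 46 named genes with a call, some lost it in limma fits with 1 array left out. Without control replicate 1, Mvd, Hspa5 and Jun had adjusted p of 0.0841 to 0.124. Without control replicate 2, Mvd, Thrsp, Nfil3, Cyp2c38, Cyp4a14, Igtp, Hspa5, Gadd45b and Jun had 0.056 to 0.165. Without control replicate 3, Zfp324, Rgs16, Ppp1r3g, Maff, Mvd, Nfil3, Cyp2c38, Socs2, Cyp4a14, Chac1, Hspa5, Jun and Plin4 had 0.055 to 0.13. Without isolated replicate 1, Rrp9, Cyp2c38 and Jun had 0.069 to 0.0745. Without isolated replicate 2, Zfp324, Mvd, Nfil3, Cyp2c38, Chac1 and Hspa5 had 0.0501 to 0.234, and without isolated replicate 3, Cxcl11, Rrp9, Zfp324, Thrsp, Cyp4a14, Igtp, Hspa5 and Jun had 0.0657 to 0.18. Some named genes without a call gained one in such fits. Ciart and Fabp4 did so in 2 fits each. In 1 fit each, Sqle, G6pc, Pck1, Hal, Nr1d2, Gstt3, Serpina4-ps1, Cebpd, Steap4, Irgm1, Hspa1a, Gclc and Mcm2 did.

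The ratio of 3′ to 5′ signal, a sign of RNA degradation, was 0.705 ± 0.014 in controls and 0.691 ± 0.0035 in isolated mice for Gapdh (exact two-sided permutation p = 0.2, n = 3 per group), and 2.21 ± 0.095 and 2.16 ± 0.18 for Actb (exact p = 0.9). The smallest p that this design allows is 0.1. The 3 control probe sets of 18S ribosomal RNA were lower on every isolated array than on every control array, with log2 differences of -0.38, -0.46 and -0.62 (exact permutation p = 0.1 for each).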

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

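The tests of explanations and of control probe sets in this part were chosen after the results were seen. The limma and camera results, normalizations and fits with 1 array left out that they draw on were planned before. A control probe set outside the comparison, for the 3′ end of the transferrin receptor transcript Tfrc, read higher on every isolated array than on every control array, at 49.8 ± 8.5 against 29.1 ± 3.67 (SD, n = 3 per group). Its log2 difference was 0.73, with an exact permutation p of 0.1, the smallest possible. Of 29 such control probe sets, 1 separated the groups upward and 3 downward, where chance gives 5% in each direction. The 3 downward ones all read 18S ribosomal RNA and are not independent, so their count cannot be judged against that share. A regular Tfrc probe set, named after its values were seen, rose 2.9-fold with a limma adjusted p of 1.64e-05.

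The PPARalpha target genes that fell and the fatty acid synthesis genes that rose in isolated mice were weighed against array scaling, fat tissue in the liver piece, feeding and time of day. Under median centring or quantile normalization 15 of the 17 called members kept their call in the fit that kept fewer, which is short of the 90% set for that test, because Cyp4a14 (log2 change -1.45 ± 0.32 SE before, -1.48 ± 0.40 after quantile normalization) and Scd2 (1.13 ± 0.28 before, 1.09 ± 0.29 after) had a similar change with a larger error. A second test, of scaling as the whole cause, was added once that value was known. In it the median change was at least 103% of its original size for the called PPARalpha genes and, slightly smaller, at least 96.2% for the called synthesis genes. That outcome was largely set in advance, as centring moved the median log2 change of all tested probe sets only from 0.035 to -0.0094. A shift of that size is small beside the changes of these genes, which argues against scaling as the whole cause. Fat tissue was first tested by the calls kept over both lists, which could not decide. For the PPARalpha genes a test on hepatocyte markers replaced it once the values were known. It uses the called genes, chosen for having fallen, while all 23 tested members had a median log2 change of -0.75. That median too is below the lowest hepatocyte marker, at -0.408. Dilution by fat tissue is argued against for the fall of the PPARalpha genes, since the 13 hepatocyte markers had a median log2 change of -0.015 and a lowest of -0.408 against a median of -1.32 for the called PPARalpha genes (with 1 array left out, -0.0594 without isolated replicate 1 to 0.0564 without isolated replicate 2, a lowest of -0.592 and -1.51 to -1.22), but fat stays open for the synthesis genes: without isolated replicates 2 and 3, which carry the Adipoq signal, 3 of the 6 kept their call in a fit that rests on 1 isolated array, assumed to vary like the controls, although 6 of 6 lay above every control on that array and their median log2 change was 1.06 against 1.16 before, and the fat markers were divided, with Fabp4 upward when adjusted over its list alone, Plin4 lower (2.69-fold, limma adjusted p 0.00695), Lipe at a log2 change of -0.16, and Lep (2.07 in controls, 1.89 in isolated mice) and Cidea (11.7 and 9.56) below the filter. More recent feeding of the isolated mice also stays open, as camera did not pass for the gluconeogenesis list, with a median log2 change of 0.15. That median was 0.0734 without control replicate 2 and 0.0895, 0.263 and 0.0869 without isolated replicates 1, 2 and 3, each in turn. The list was divided, so its median says little on feeding. Of its 21 tested members 14 lay above 0, Hal (0.60) and Got1 (0.63) among them, and 7 below, G6pc (-0.66) and Pck1 (-0.41) among them. Sampling at another time of day stays open too (mixed p 0.20 from fry for the clock list, 0.104 to 0.536 with 1 array left out). Feeding and time of day cannot be told apart from the differences that the labels name, single housing and less bedding, which are themselves confounded with each other.

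Probe sets of the same gene disagreed for Car3 and Alad, both named after their values were seen. Dim Car3 probe sets rose by log2 3.28 and 3.94 (3.19 for the latter without control replicate 2) while bright ones were at -0.02 and -0.0016, and a dim Alad probe set rose by 2.51 while the bright one had a change of 0.15. Saturation is argued against for the bright Alad probe set, since 11 of the 821 probe sets at least as bright were called (9 to 14 with 1 array left out). For Car3 saturation stays open, since of 48 probe sets at least as bright as its bright ones 0 were called with a change of 2-fold or more, and none of them need have changed. Fat tissue stays open too: without isolated replicates 2 and 3 the dim Car3 probe sets had a mean log2 change of 3.76, which rests on 1 isolated array, and a change in a transcript form that only the dim probe sets read was not tested.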

How the results depend on the processing

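The fit without isolated replicates 2 and 3 was chosen after seeing the data, and the others before. Probe sets higher and lower numbered 174 and 193. They numbered 81 and 101 without a filter, 15 and 16 without the intensity trend, and 0 and 0 with an unmoderated equal-variance test per probe set, which gave 1980 at an unadjusted p under 0.05 (limma gave 1552 higher and 1020 lower). Higher calls rose to 303 at an adjusted p under 0.1, with 285 lower. Without isolated replicates 2 and 3, 88 were higher and 202 lower, and 173 of the 290 calls were shared with the original 367. With 1 array left out, higher calls ranged from 97 (without isolated replicate 3; 115 without control replicate 2) to 187, and lower calls from 82 (without control replicate 3) to 243. The other settings stayed within 1.5 times, except the replicate number as a block, with 265 higher and 248 lower. Deviations of same-numbered samples correlated at 0.0078, 0.044 and 0.0049. Numbers 2 and 3 correlated best with their own number, and number 1 with number 3. Values this near 0 show no clear pairing by number, and so few samples cannot exclude a pairing or a shared batch. Calls that were higher made up 47.4% at the deposited scale, 38% with centring and 37.9% with quantile normalization.

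The 9 pathway lists and 1 marker list that passed camera numbered 0 and 0 with an estimated correlation and 0 and 0 by fry. Marker lists numbered 2 without a filter and 0 with array weights or without isolated replicates 2 and 3. With 1 array left out, pathway lists ranged from 7 to 13 and marker lists from 0 to 2. The RNA quality ratios kept their direction with 3′ over middle probe sets. Of the 46 named genes with a call, 9 kept it without the trend, 28 without a filter, 29 with a robust trend, 34 with quantile normalization and 37 with median centring. Car3 went from a log2 change of -0.02 to 1.80 when all its probe sets were averaged, as its dim probe sets then enter. The causes of the other changes were not tested. Of the 6 arrays, 10 splits into 2 groups of 3 exist, too few for a share under 0.05. The real split gave 367 calls and the highest other 1, so 1 split gave as many. For lists, the real split gave 10 and the highest other 12, and 4 splits gave as many. Under both normalizations calls were lost by dim genes (Cxcl11, Zfp324, Maff) and by brighter ones (Hspa5, Creld2, Socs2). Probe sets below the signal floor, Adipoq among them, were not tested.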

Other observations

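Of the 23 tested genes of the unfolded protein response, 20 had log2 changes above 0. The 3 below 0 were Chac1, which fell, Asns at -1.20 ± 0.36 (SE, limma adjusted p 0.108) and Xbp1 at -0.14 ± 0.14 (limma adjusted p 0.808), the last 2 named after their values were seen.

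Ppp1r3c, a glycogen-targeting phosphatase subunit named after its values were seen, rose 2.88-fold with a limma adjusted p of 0.002, while Ppp1r3g of the same family fell 6.09-fold. Among called genes with at least 2 tested probe sets, 141 in number, 17 had a probe set of opposite sign and 0 had calls in both directions.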
